A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

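RNA sequencing libraries from 18 yeast samples were compared, 3 from each of 6 groups: wild type, msn2 deletion and msn2 msn4 double deletion, each young (exponential growth) or aged (24 h in a Ministat Aging Device). Per the labels, aged mothers carried biotin and were held on magnetic beads, polyA RNA with an RNA integrity number above 6 was made into libraries with the NEB Ultra II Directional kit, and paired reads were sequenced on a NovaSeq X Plus. The authors name bcl2fastq, cutadapt 2.6, STAR 2.7.6a and featureCounts of Subread 1.6.2 with genome build R64 (sacCer3), and do not state the counting options.
The deposited table holds expected counts, that is, estimated counts with fractions, for 7118 genes and other features in all 18 libraries. Of the values above 0, 54.6% were not whole to the 2 decimals given, so reads were shared between features in some way, and values were rounded before the edgeR fit. Values were not scaled to depth. Library totals ran from 4078400 to 41649952 counts, and counting error was part of the fitted spread. In all, 6040 identifiers matched locus tags of the reference annotation, from which chromosome, start and end were taken, and 1078 did not, including 91 Ty element features. The library kit keeps strand, but YGL102C, a dubious gene known to overlap RPL28 on the opposite strand and without coordinates in the annotation used, had a median count of 175407 against 179053 for RPL28. Counts of overlapping genes may therefore not be separable. The annotation places 7 other genes inside a gene of the opposite strand, and sharing was not shown for each of them.
All 18 libraries were fitted together with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr, which kept 6833 genes and left out 285, and 1 mean per group, which leaves 12 residual degrees of freedom. The common biological coefficient of variation was 0.0922 and the median prior degrees of freedom 7.72. Quasi-likelihood F tests, which are two-sided, were run for 12 contrasts: aged against young in each strain, each pair of strains at each age, and the 3 differences of age effects between strains. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, and a second count took those with an absolute log2 fold change of at least 1. Group levels are CPM with TMM factors, given as mean and SD over 3 libraries.
In each contrast 35 gene lists, written from textbook knowledge, were tested with camera of limma 3.58.1 at a preset correlation of 0.01. They were adjusted over the 34 lists with at least 2 tested members. Camera with a correlation estimated for each list, and fry, were run beside it. Fry tests whether a list's genes move on balance one way, without comparing them with other genes. Correlations across genes were computed for the age effects of each pair of strains and for the deletion effects, and the latter were set beside 20 simulated draws with no deletion effect, seed 20. Lists, tests, contrasts and alternatives were fixed before the data were examined, except those named here and in the closing section as added later.
Named genes followed a rule. MSN2 and MSN4 are given in every group. For each contrast the 8 highest and 8 lowest log2 fold changes were taken among genes that passed, with a mean log2 CPM of at least 3 and, in contrasts of a pair of groups, no overlap between replicates; chance gives no overlap for 10% of genes with 3 against 3. Up to 4 members of each list with the smallest p in the contrast were taken, a gene named for 1 contrast could be given in others, and 20 genes were fixed: CTT1, HSP12, HSP26, TPS1, FIT2, FIT3, FET3, HXT3, HXT7, RPL3, NSR1, CIT1, COX1, RNR3, CTS1, DSE2, MFA1, STE3, BIO5 and HTB1. Genes of the ribosomal DNA other than RRT15, RDN5-1 and ETS2-2, the neighbours of RRT15 and the members of a list of oxygen-linked genes were chosen after their values were seen.
The alternatives were DESeq2 1.42.0, RLE factors or library totals in place of TMM, no filter, a filter of at least 10 CPM in 3 libraries, removal of mitochondrially encoded, ribosomal RNA and Ty genes, replicate number as a block, only the libraries of the contrast, a test against a log2 fold change of 0.5, each library left out in turn, correlations over genes with a mean log2 CPM of at least 5, and wild-type libraries divided between comparisons. Thinning of all libraries to the smallest total and a fit without the 3 aged double deletion libraries were added after the data were seen. So was removal of RRT15, which was taken out only together with the mitochondrially encoded, ribosomal RNA and Ty genes. Labels give no batch or day. Residual correlations of 45 pairs of libraries with the same replicate number had a median of -0.0568, and 17 were over 0.1, so the numbers did not pair libraries over all groups. Between young and aged wild type the 3 correlations were 0.243, 0.508 and 0.227, all over 0.1, and between young msn2 deletion and aged wild type, which were not compared, 0.12, 0.421 and 0.399.
The pipeline was tested on simulated data with 200 changed genes. In the age contrast of wild type it recovered 73.1% of genes changed by 0.5 on the log2 scale, 97% by 1 and 100% by 2, and 62.7%, 88.1% and 97% in the aged double deletion against wild type. In the difference of age effects between double deletion and wild type it recovered 29.9%, 88.1% and 98.5%. It called 6 to 9 of about 6590 unchanged genes. The real data called far more genes in these contrasts of wild type age, aged double deletion and difference of age effects: 4365, 2478 and 1104. The adjusted p threshold depends on how many genes change, so the simulated recoveries and false calls do not carry over to the real counts.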

Results

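RNA was sequenced from 18 budding yeast samples in 6 groups of 3 replicates. Wild-type cells, cells lacking the stress transcription factor gene MSN2, and cells lacking MSN2 and its close relative MSN4 were each harvested young, from exponential cultures, or aged. Aged cells were mother cells held on magnetic beads for 24 h in a Ministat Aging Device, a chamber in which fresh medium flows past the beads and carries daughter cells away. All strains were MAT alpha and grew in biotin-free synthetic complete medium with 2% glucose at pH 4.5. Library totals were 30140441 to 35101890 counts in young wild type, 25768602 to 34344784 in young msn2 deletion and 27698098 to 33651287 in young double deletion. Aged wild type had 29230104 to 41649952 counts and aged msn2 deletion 38301372 to 41160297, whereas the aged double deletion had 4078400 to 7136185. One strain stands for each genotype, and no label says that replicates were separate cultures, so p-values measure the spread between these samples. Aged and young cells also differ in growth mode, in bead labelling and in RNA from selected mothers against whole cultures, so every age comparison covers these differences too. In the first 2 principal components, which held 64.3% and 20% of the variance, the first separated aged from young libraries and the second ordered the strains within each age.
The counts of the deleted genes were compared first. MSN2 (YMR037C, chromosome XIII, 344403 to 346517, build R64) stood at 41.7 ± 2.89 CPM (mean ± SD, n = 3 in every group) in young wild type. It stood at 4.29 ± 0.127 in young msn2 deletion and 3.57 ± 0.942 in the young double deletion. In aged cells MSN2 was 33.4 ± 1.83 CPM in wild type, 4.11 ± 0.443 in msn2 deletion and 4.28 ± 0.616 in the double deletion. MSN4 (YKL062W, chromosome XI, 323228 to 325120) was 42.6 ± 2.76 CPM in young wild type, 50.6 ± 5.79 in young msn2 deletion and 21.4 ± 3.01 in the young double deletion. In aged cells MSN4 was 51.5 ± 2.38 CPM in wild type, 84.1 ± 2.44 in msn2 deletion and 13.4 ± 1.29 in the double deletion. MSN2 was thus low in both deletion strains, while MSN4 in the double deletion was lower than in wild type but well above 0. MSN4 was higher in aged msn2 deletion than in aged wild type (log2 0.71 ± 0.0926 SE), while the young difference did not pass (log2 0.25 ± 0.0955). Counts per gene do not show which part of MSN4 the reads left in the double deletion cover.

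**Figure D1:**
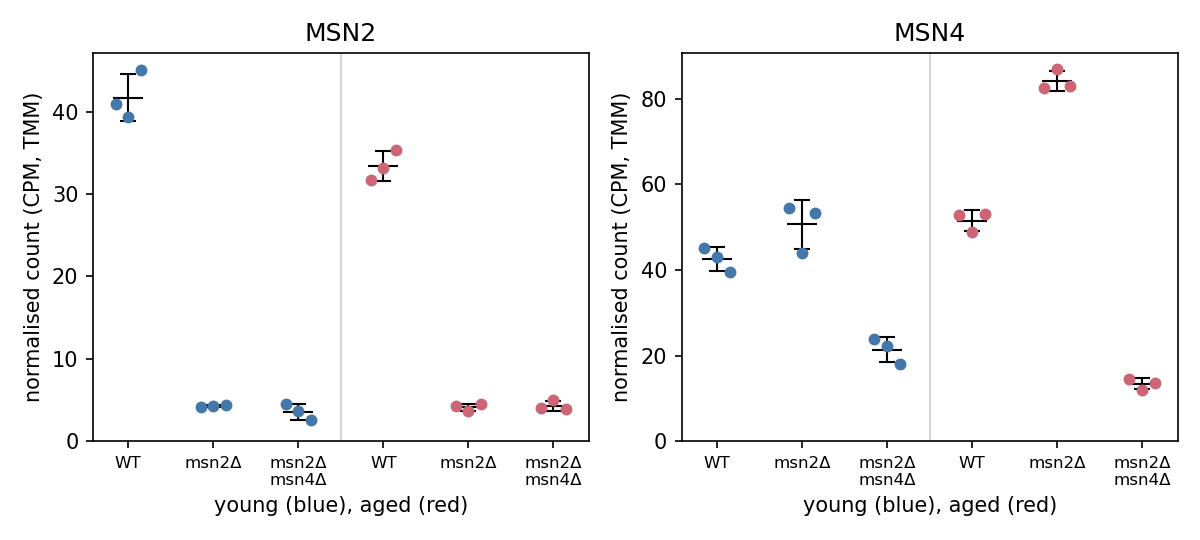
Normalised counts (CPM with TMM factors) of MSN2 and MSN4 in each library, by strain, for young (blue) and aged (red) cells. Points are libraries, the long bar is the group mean and the short bars are 1 SD; MSN2 stays at 4.29 CPM or less in the means of both deletion strains, and MSN4 reaches 84.1 CPM in aged msn2 deletion.

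The first comparison asked which transcripts differ between aged and young wild-type cells. General stress genes, zinc uptake genes and hexose transporters were higher in aged cells. Most cytosolic ribosomal protein genes were lower, a list call that was lost with an estimated correlation (adjusted p = 0.122 with an estimated correlation). Values below are log2 fold changes ± SE from 3 libraries a group. The largest rise was in ZPS1 (YOL154W, chromosome XV, 34658 to 35407), a secreted protein of the zinc response, at 6.80 ± 0.151: its level was 2230 ± 82.7 CPM aged and 20.1 ± 2.11 CPM young. ZRT1, the high-affinity zinc transporter (YGL255W, chromosome VII, 20978 to 22108), rose by 6.33 ± 0.119, and TDH1, an isoform of glyceraldehyde-3-phosphate dehydrogenase (YJL052W, chromosome X, 338271 to 339269), by 5.35 ± 0.102. HSP26, a small heat shock protein (YBR072W, chromosome II, 382030 to 382674), rose by 4.55 ± 0.114, and BSC1 and YOR387C by 5.12 ± 0.207 and 4.76 ± 0.134. Among protein-coding genes that met the naming rule, the strongest falls were in YLR108C (-2.57 ± 0.102), YGR035C (-2.24 ± 0.16), ZEO1 (-2.09 ± 0.208), the meiotic gene ZIP1 (-1.99 ± 0.136) and the glucose-dependent repressor gene MIG2 (-1.86 ± 0.11). The 5S ribosomal RNA gene RDN5-1 and ETS2-2, an external transcribed spacer of the ribosomal DNA, were also higher, by 5.34 ± 0.233 and 5.74 ± 0.206.
Of 51 Msn2/4 stress genes, 49 rose and 0 fell, with a median of 1.21 (camera adjusted p = 3.24e-45, and 0.000115 with an estimated correlation). The list holds HSP26, GND2 (3.31 ± 0.119) and the chaperone gene SSA4 (2.25 ± 0.0732), and its members CTT1 for catalase T, HSP12 and TPS1 for trehalose synthesis rose by 0.99 ± 0.122, 1.25 ± 0.139 and 1.59 ± 0.145. Zinc genes rose in 11 of 12 cases (adjusted p = 2e-27, and 0.0007 with an estimated correlation). Hexose transporters rose in 13 of 16 and fell in 2 (adjusted p = 2.56e-07, and 0.00203 with an estimated correlation): HXT4 by 4.34 ± 0.12, HXT7 by 2.59 ± 0.114 and HXT3 by 1.51 ± 0.123. HXT6 and HXT7 are nearly identical in sequence, and how reads that match both were counted is unknown. These 3 lists held with an estimated correlation, and the 14 other camera calls of this comparison did not.
Among those 14, the list of cytosolic ribosomal proteins fell in 122 of 139 genes and rose in 2 (median -0.75, camera adjusted p = 8.97e-23), as RPL9A (-1.46 ± 0.133) and RPL33A (-1.25 ± 0.118) show, while RPL3 was at -0.14 ± 0.0912 with an adjusted p of 0.175. The symbol pattern behind this list also matches RPP1, an RNase P subunit gene, so not all 139 are ribosomal protein genes. Mitochondrial ribosomal proteins fell in 43 of 66 and rose in 4 (adjusted p = 0.326 with an estimated correlation). Histone genes fell in 8 of 10 (adjusted p = 0.122 with an estimated correlation), HTA2 at -1.18 ± 0.114 and HTB1 at -0.59 ± 0.0844. Hsf1 chaperones fell in 15 of 22 and rose in 2 (adjusted p = 0.122 with an estimated correlation), with SSA2 at -1.17 ± 0.111 and STI1 at -0.89 ± 0.0843. The TCA cycle rose in 11 of 12 (adjusted p = 0.166 with an estimated correlation), with LSC2 at 1.25 ± 0.0834 and CIT1, citrate synthase, at 1.06 ± 0.117. Gluconeogenesis genes rose in 12 of 18 (adjusted p = 0.109 with an estimated correlation), CIT2 by 1.55 ± 0.0808. Glycolysis genes rose in 6 and fell in 3 of 17 (adjusted p = 0.572 with an estimated correlation): the minor isoforms TDH1 and ENO1 (3.11 ± 0.101) rose, and ADH1, the main alcohol dehydrogenase, fell (-1.50 ± 0.104).
The iron regulon rose in 21 of 30 and fell in 3 (adjusted p = 0.259 with an estimated correlation), with the cell wall mannoproteins FIT2 at 41.6 ± 2.46 CPM aged against 9.67 ± 0.686 CPM young and FIT3 at 2.38 ± 0.155, and the iron oxidase gene FET3 at -0.12 ± 0.101 with an adjusted p of 0.297. Cell wall stress genes rose in 12 of 15 and fell in 2 (adjusted p = 0.166 with an estimated correlation), the glucan synthase gene GSC2 by 2.03 ± 0.118 and PIR3 by 2.68 ± 0.162. Amino acid biosynthesis genes rose in 27 of 44 and fell in 4 (adjusted p = 0.468 with an estimated correlation), with GLN1 at 1.40 ± 0.0786. Biotin genes rose in 7 of 9 and fell in 1 (adjusted p = 0.166 with an estimated correlation), with BIO5, a transporter of a biotin precursor, at 1.06 ± 0.119. The ergosterol list rose in 18 of 28 and fell in 2 (adjusted p = 0.326 with an estimated correlation); its leaders TIR1 (2.26 ± 0.154) and DAN1 (4.29 ± 0.299) are cell wall mannoproteins known to be made without oxygen, and ERG1 of sterol synthesis rose by 0.88 ± 0.115. COS genes rose in 8 of 12 (adjusted p = 0.166 with an estimated correlation) and autophagy genes in 12 of 19, with 3 lower (adjusted p = 0.129 with an estimated correlation). Most COS and PAU genes belong to families of near-identical members, and how reads that match several of them were counted is unknown. The symbol pattern behind the COS list also matches COS111 (chromosome II, 629168 to 631942), whose likeness to the others was not checked.
The other 17 testable lists had no camera call in aged wild type. Ribosome biogenesis rose in 30 and fell in 35 of 97 genes, with its median at 0.00848, above 0, and its test pointing down (adjusted p = 0.348); NSR1, a nucleolar protein gene, rose by 0.32 ± 0.0719. Nuclear respiratory chain genes rose in 16 and fell in 10 of 38, and mitochondrially encoded genes rose in 0 and fell in 3 of 8, with COX1 at -0.02 ± 0.206, which did not pass. Fatty acid oxidation genes rose in 6 and fell in 6 of 18, proteasome genes in 15 and 7 of 33, and DNA damage genes in 11 and 3 of 17, among them the ribonucleotide reductase gene RNR3 at 1.44 ± 0.182. G1/S genes rose in 3 and fell in 7 of 21, and G2/M genes in 2 and 5 of 16. Meiosis genes rose in 6 and fell in 4 of 20, PAU genes rose in 10 of 17, and Pho4 phosphate genes rose in 8 and fell in 2 of 18. Sulfur genes rose in 8 and fell in 6 of 25, and drug efflux genes in 6 and 2 of 11.
Markers of daughter cells and of mating type were read as checks on what the samples held. Daughter-cell genes rose in 6 and fell in 1 of 12, with the chitinase gene CTS1 at 0.37 ± 0.128 and DSE2 at 0.11 ± 0.0971, not past the test. Alpha-specific genes rose in 1 and fell in 2 of 4: MF(ALPHA)2 fell by 1.57, and STE3 was at -0.02 ± 0.085. Genes specific to a cells rose in 3 of 6, with MFA1, an a-factor gene, at 2.72 ± 0.203 CPM aged against 1.13 ± 0.361 CPM young. Haploid and pheromone genes rose in 10 and fell in 2 of 16. Of the 4 genes at the silent mating loci, 1 passed the count filter, HMLALPHA2 at -1.22 ± 0.462. It lay near the floor, at 0.224 ± 0.0212 CPM aged against 0.533 ± 0.254 CPM young. How reads that match other places were counted is unknown, so HMLALPHA2 gives no check on the silent loci.
In all, 4365 of 6833 tested genes differed between aged and young wild type, 2272 higher and 2093 lower, and 757 differed at least 2-fold, 421 higher and 336 lower. Against a log2 fold change of 0.5, 1283 genes passed. Counts adjusted over the list alone equalled those above for all lists but 6: 123 lower cytosolic ribosomal proteins, 17 higher and 11 lower respiratory genes, 2 lower mitochondrially encoded genes, 7 higher and 7 lower fatty acid genes, 3 lower haploid genes and 9 higher COS genes. The scaling sets the balance of directions. With library totals in place of TMM factors the median of all genes moved by 0.51 in wild type, 0.59 in msn2 deletion and 0.43 in the double deletion, and 4753 wild-type genes were then called higher and 598 lower; directions here are relative to that median.
The same comparison in msn2 deletion cells also showed higher zinc and stress genes, some by more and some by less than in wild type. ZPS1 rose by 6.80 ± 0.151, TDH1 by 6.33 ± 0.108, ZRT1 by 6.05 ± 0.117 and the protein kinase gene RCK1 by 5.36 ± 0.168. Of 51 Msn2/4 stress genes 48 rose and 1 fell, with a median of 1.43: HXK1, a hexokinase, rose by 4.15 ± 0.149, HSP12 by 3.72 ± 0.156 from 25.5 ± 7.48 to 335 ± 28.8 CPM, and HSP26 by 3.47 ± 0.112, while CTT1 rose by 0.42 ± 0.131. Hexose transporters rose in 13 of 16, HXT7 by 4.49 ± 0.136, and gluconeogenesis genes in 16 of 18, CRC1 by 2.97 ± 0.261. Hsf1 chaperones fell in 19 of 22, with the Hsp110 gene SSE1 at -1.31 ± 0.0885 and HSP10 at -1.76 ± 0.19. All 4 alpha-specific genes fell, with STE3 at -0.79 ± 0.0852, and daughter-cell genes fell in 4 and rose in 1 of 12, with DSE4 at -0.60 ± 0.0767. Cytosolic ribosomal proteins fell in 113 of 139 (adjusted p = 0.139 with an estimated correlation).
Lists called in msn2 deletion with an estimated correlation were Msn2/4 stress genes (adjusted p = 0.000169), zinc (0.00532), hexose transporters (0.00532), gluconeogenesis (0.0104), Hsf1 chaperones (0.0171) and alpha-specific genes (0.0496). Camera with the preset correlation called 19 of 34. The gene test found 4754 genes, 2501 higher and 2253 lower, and 1008 of them at least 2-fold changed; 1899 passed against a log2 fold change of 0.5. When scaled by library totals alone, 4927 were higher and 645 lower. Adjusted over the list alone, counts of the lists named here were the same except 14 higher hexose transporters, 1 lower zinc gene and 114 lower ribosomal proteins.
Aged double deletion cells also had higher zinc, stress and hexose transporter genes than young ones. ZPS1 rose by 8.22 ± 0.16, from 18 ± 1.75 to 5360 ± 574 CPM, ZRT1 by 6.60 ± 0.12, and the subtelomeric genes YOR387C and VEL1 by 6.91 ± 0.144 and 6.39 ± 0.119. Among the 51 Msn2/4 stress genes, 33 rose and 4 fell, with a median of 0.73: HSP12 rose by 3.28 ± 0.161 and HSP26 by 2.33 ± 0.114, and CTT1 was at 0.00 ± 0.174, with no call. Ribosome biogenesis genes rose in 64 of 97 and fell in 14 (adjusted p = 0.195 with an estimated correlation), IMP4 by 1.17 ± 0.094. Hsf1 chaperones fell in 18 of 22. The alcohol dehydrogenase gene ADH1 was lower at -2.18 ± 0.106. The a-specific genes rose in 4 of 6 (adjusted p = 0.216 with an estimated correlation), MFA1 by 3.29 ± 0.284 to 5.62 ± 1.25 CPM.
RRT15, a small predicted gene near the ribosomal DNA (YLR162W-A, chromosome XII, 490406 to 490594), rose by 11.82 ± 0.302, from 0.85 ± 0.132 CPM young to 3080 ± 525 CPM aged. Its first 137 of 189 bases are 98.5% identical to 25S ribosomal DNA, on the strand opposite the ribosomal RNA, and the nuclear ribosomal RNA gene RDN18-1 was also higher in these 3 libraries, at 11.1 ± 1.22 CPM against 1.73 ± 0.215 CPM in aged wild type.

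**Figure D2:**
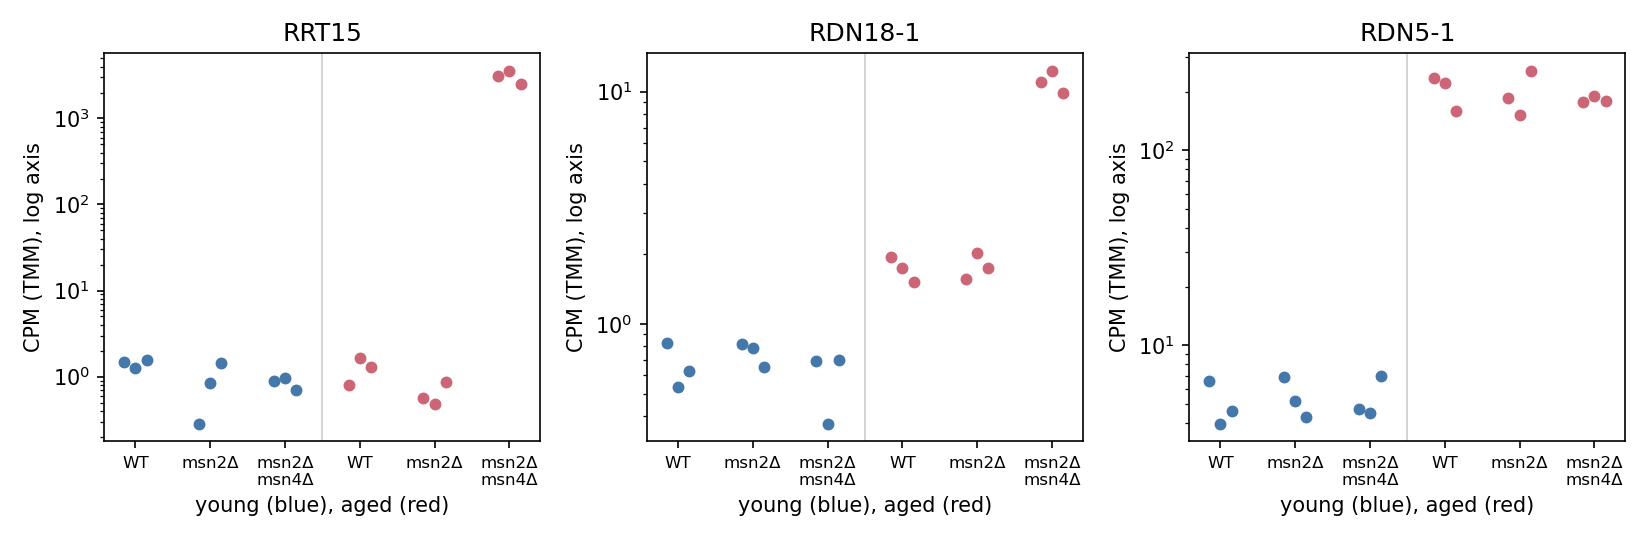
Normalised counts (CPM with TMM factors, log axis) of RRT15, RDN18-1 and RDN5-1 in each library, by strain and age. Points are libraries; RRT15 sits between 2540 and 3590 CPM in the 3 aged double deletion libraries and at 1.65 CPM or less in the other 15, whereas RDN5-1 is higher in aged cells of all strains.

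Estimated correlations kept 4 lists in the aged double deletion: Msn2/4 stress genes (adjusted p = 0.00883), hexose transporters (0.00883), Hsf1 chaperones (0.0112) and zinc (0.000671). Camera called 19. The gene test found 4179 genes, 2135 higher and 2044 lower, with 786 at least 2-fold changed and 1334 past a log2 fold change of 0.5. Under library totals alone 4104 were higher and 827 lower. When adjusted over the list alone, 35 stress genes were higher and 4 lower, and 65 biogenesis genes were higher.
Age effects resembled each other across strains. Over 6833 genes, which are not independent replicates, the log2 fold changes of wild type and msn2 deletion correlated at Pearson r = 0.871 and Spearman rho = 0.857, those of wild type and double deletion at 0.798 and 0.793, and those of both deletion strains at 0.846 and 0.873. Of 2272 genes higher in aged wild type, 1818 were also higher in aged msn2 deletion, where independent calls would share 832, and 1532 in the aged double deletion, where they would share 710. Among lower genes, 1675 were shared with msn2 deletion and 1525 with the double deletion, against 690 and 626.
In young cells, most Msn2/4 stress genes were lower in msn2 deletion than in wild type. HSP12, a membrane-binding stress protein (YFL014W, chromosome VI, 107256 to 107585), fell by 4.78 ± 0.163 on the log2 scale, from 697 ± 89.9 to 25.5 ± 7.48 CPM. HXK1 was lower at -4.08 ± 0.15, DDR2 at -4.01 ± 0.181, RTC3 at -3.79 ± 0.127, the trehalose synthase subunit gene TSL1 at -2.65 ± 0.0845 and HOR7 at -2.63 ± 0.152. Of 51 Msn2/4 stress genes 41 fell and 1 rose, with a median of -1.03. The nuclear respiratory chain fell in 24 of 38, RIP1 at -0.88 ± 0.086 and NDI1 at -0.66 ± 0.0697. All 10 histone genes fell, with HTB1 at -0.79 ± 0.0848. HXT7 was lower at -2.16 ± 0.143 and HXT3 rose by 0.81 ± 0.121.
Genes with higher counts in young msn2 deletion included COS12 (2.37 ± 0.164), a subtelomeric gene, and SAG1, the alpha agglutinin (1.31 ± 0.0922). How reads that match both COS12 and its relatives were counted is unknown. Alpha-specific genes rose in 3 of 4, with STE3 at 0.89 ± 0.0856, and haploid and pheromone genes in 6 of 16, with FUS1 at 0.79 ± 0.0927. Daughter-cell genes rose in 10 of 12 (adjusted p = 0.182 with an estimated correlation), DSE4 by 0.90 ± 0.0775 and CTS1 by 0.45 ± 0.128, and zinc genes in 9 of 12 (adjusted p = 0.0987 with an estimated correlation). Mitochondrially encoded genes rose in 6 of 8 (adjusted p = 0.539 with an estimated correlation), COX1 by 0.76 ± 0.207. Cytosolic ribosomal proteins fell in 57 of 139 (adjusted p = 0.548 with an estimated correlation).
With an estimated correlation the called lists were Msn2/4 stress genes (adjusted p = 1.53e-06), alpha-specific genes (0.00696), and the respiratory chain, histones and haploid genes, each at 0.0411. Camera called 11. The gene test found 2084 genes, 1023 higher and 1061 lower, and 120 at least 2-fold changed, 42 higher and 78 lower; 139 passed against a log2 fold change of 0.5, and 1279 once all libraries were thinned to the smallest total. With library totals alone 1056 were higher and 674 lower. Adjusted over the list alone, 44 stress and 63 ribosomal protein genes fell and 7 haploid genes rose.
The young double deletion differed from young wild type in much the same genes. HSP12 stood at -6.13 ± 0.176, HXK1 at -4.96 ± 0.162, RTC3 at -4.95 ± 0.139 and DDR2 at -4.92 ± 0.198. Among the 51 Msn2/4 stress genes, 41 fell and 1 rose, with a median of -1.15. The nuclear respiratory chain fell in 29 of 38, and histones in 10 of 10 (adjusted p = 0.0652 with an estimated correlation). PHO84, the high-affinity phosphate transporter (YML123C, chromosome XIII, 24037 to 25800), rose by 1.93 ± 0.114, from 13.2 ± 1.96 to 50.3 ± 3.15 CPM, and PHO12, an acid phosphatase, by 1.31 ± 0.145; an antisense transcript is annotated opposite PHO84, and whether its reads were counted with PHO84 is unknown. Pho4 genes rose in 10 and fell in 3 of 18 (adjusted p = 0.07 with an estimated correlation). Amino acid biosynthesis genes rose in 23 of 44 (adjusted p = 0.459 with an estimated correlation). Daughter-cell genes rose in 11 of 12 (adjusted p = 0.0851 with an estimated correlation) and alpha-specific genes in 3 of 4, SAG1 by 1.38 ± 0.0923.
Lists called with an estimated correlation were Msn2/4 stress genes (adjusted p = 1.64e-06), alpha-specific genes (0.0167) and the respiratory chain (0.0337), of 13 called by camera. The gene test found 2579 genes, 1221 higher and 1358 lower, with 154 at least 2-fold changed, 35 higher and 119 lower, and 193 past a log2 fold change of 0.5. When scaled by library totals alone, the median moved by 0.17, and 2005 genes were higher and 681 lower. When adjusted over the list alone, 42 stress, 30 respiratory, 24 amino acid and 12 daughter-cell genes passed.
Few genes differed between the double deletion and msn2 deletion in young cells. PHO84 was higher in the double deletion than in msn2 deletion by 2.09 ± 0.116, and PHO12 by 1.07 ± 0.143. HSP12 was lower at -1.36 ± 0.155, RTC3 at -1.16 ± 0.157, STF2, which acts on ATP synthase, at -1.11 ± 0.181, HOR7 at -1.11 ± 0.145 and COX5B at -0.80 ± 0.116. Msn2/4 stress genes fell in 8 of 51, and in 17 adjusted over the list alone, with a median of -0.14. Pho4 genes rose in 4 of 18, and in 6 adjusted over the list alone. Amino acid biosynthesis genes rose in 2 of 44, and in 15 adjusted over the list alone (adjusted p = 0.139 with an estimated correlation). Of glycolysis genes 0 of 17 rose, and 13 did so adjusted over the list alone (adjusted p = 0.285 with an estimated correlation).
The lists of Msn2/4 stress genes (adjusted p = 0.0161) and Pho4 genes (1.62e-05) held with an estimated correlation, of 14 camera calls. The test found 31 genes, 9 higher and 22 lower, 8 of them at least 2-fold changed and 6 past a log2 fold change of 0.5. This count depended on the method: DESeq2 called 85, which included the 31, library totals alone gave 10 higher and 9 lower after a shift of the median by 0.12, a fit of these 6 libraries alone gave 13, thinning gave 16, and leaving out any of the 6 libraries gave 14 to 19.
Across genes the effects of both deletions on young cells correlated at Pearson r = 0.833 and Spearman rho = 0.82. They share wild-type libraries, which alone gave a mean r of 0.499 in simulated data without a deletion effect. Their covariance was 0.149 against a simulated 0.015, and dividing the wild-type libraries between the comparisons gave r of 0.44 to 0.682. Of 1023 and 1221 genes higher in each, 807 were shared, against 183 for independent calls, and of 1061 and 1358 lower, 877, against 211; these overlaps share controls as well.
In aged cells, msn2 deletion again lowered stress genes. Besides MSN2, the lower genes included HSP12 (-2.31 ± 0.143, from 1660 ± 105 to 335 ± 28.8 CPM), TSL1 (-2.25 ± 0.0797), RTC3 (-2.15 ± 0.108) and the plasma membrane stress protein gene HSP30 (-2.11 ± 0.0792). Of 51 Msn2/4 stress genes 43 fell and 1 rose, with a median of -0.88; CTT1 stood at -1.72 ± 0.123, HSP26 at -1.58 ± 0.0967 and TPS1 at -1.38 ± 0.143. Histones fell in 9 of 10, with HTA2 at -0.80 ± 0.114. Proteasome genes fell in 19 of 33 (adjusted p = 0.0773 with an estimated correlation), with RPN11 at -0.59 ± 0.0923, and respiratory chain genes in 19 of 38 (adjusted p = 0.0709 with an estimated correlation).
RCK1 was higher in aged msn2 deletion by 1.89 ± 0.128, ARG3 of arginine synthesis by 1.57 ± 0.0948, the thiamine genes THI7 and THI4 by 1.39 ± 0.0878 and 1.37 ± 0.118, and PHO84 by 1.06 ± 0.109. Gluconeogenesis genes rose in 10 of 18, JEN1 by 0.68 ± 0.112, and PAU genes in 8 of 17. Several PAU genes lay near the floor. Their mean log2 CPM over all libraries was 1.26 for PAU5, 0.435 for PAU24, -0.687 for PAU19 and -1.17 for PAU9. Ribosome biogenesis genes rose in 53 of 97 (adjusted p = 0.149 with an estimated correlation). Amino acid biosynthesis genes rose in 10 and fell in 3 of 44 with a median of 0.0129 (adjusted p = 0.594 with an estimated correlation); the median was -0.00287 with RLE factors and -0.0163, -0.0167 or -0.029 without aged wild type replicate 2, aged msn2 deletion replicate 1 or aged msn2 deletion replicate 2.
Lists called with an estimated correlation were Msn2/4 stress genes (adjusted p = 5.91e-06), PAU genes (0.0173), histones and gluconeogenesis (both 0.0312), of 15 called by camera. The gene test found 2047 genes, 952 higher and 1095 lower, with 134 at least 2-fold changed, 78 higher and 56 lower, and 170 past a log2 fold change of 0.5. Under library totals alone the median moved by 0.13, and 1658 genes were higher and 507 lower. Adjusted over the list alone, 25 proteasome, 21 respiratory, 12 gluconeogenesis, 11 PAU and 55 biogenesis genes passed in those directions.
The aged double deletion was further below aged wild type in Msn2/4 stress genes than msn2 deletion was. SOL4 of the pentose phosphate pathway (YGR248W, chromosome VII, 985972 to 986739) was at -4.52 ± 0.157, from 49.3 ± 2.38 to 2.25 ± 0.687 CPM, RGI1 at -4.36 ± 0.21, HSP12 at -4.10 ± 0.158, GPH1 at -3.86 ± 0.119, HXK1 at -3.78 ± 0.143 and STF2 at -3.65 ± 0.202. Among the 51 Msn2/4 stress genes, 48 fell and 0 rose, with a median of -2.17; TSL1 was at -3.58 ± 0.0963, PGM2 at -3.10 ± 0.0976, CTT1 at -2.44 ± 0.156 and HSP26 at -2.46 ± 0.105. The nuclear respiratory chain fell in 33 of 38, with NDI1 at -1.06 ± 0.0744, and proteasome genes in 23 of 33 (adjusted p = 0.137 with an estimated correlation). Biotin genes fell in 6 of 9 (adjusted p = 0.0706 with an estimated correlation), with BIO3 at -1.18 ± 0.0696 and BIO5 at -1.04 ± 0.127. HXT7 was lower at -1.74 ± 0.119 and HXT4 at -1.12 ± 0.105.
Besides RRT15 (11.23 ± 0.286), higher genes included VEL1 (1.98 ± 0.0936), PHO84 (1.81 ± 0.117), YOR387C (1.80 ± 0.105), FCY2, a purine and cytosine permease (1.27 ± 0.142), and ZPS1 (1.26 ± 0.117). Ribosome biogenesis genes rose in 74 and fell in 3 of 97 (adjusted p = 0.0604 with an estimated correlation), DBP8 by 0.96 ± 0.0727 and NSR1 by 0.43 ± 0.0722. Amino acid biosynthesis genes rose in 28 of 44 (adjusted p = 0.271 with an estimated correlation) and zinc genes in 9 of 12 (adjusted p = 0.0706 with an estimated correlation). In the same libraries daughter-cell genes rose in 10 of 12 (adjusted p = 0.257 with an estimated correlation), CTS1 by 0.67 ± 0.129, and alpha-specific genes in 3 of 4 (adjusted p = 0.0706 with an estimated correlation). The 3 aged double deletion libraries have the lowest totals, 4078400 to 7136185 counts.
The lists of Msn2/4 stress genes (adjusted p = 1.67e-06) and the respiratory chain (0.022) held with an estimated correlation, of 14 camera calls. The gene test found 2478 genes, 1133 higher and 1345 lower. At least 2-fold changed were 266, of which 43 were higher and 223 lower, and 390 passed against a log2 fold change of 0.5. With library totals alone 1344 genes were higher and 995 lower. When adjusted over the list alone, 49 stress, 34 respiratory, 25 proteasome and 76 biogenesis genes passed in those directions.
In aged cells 1696 genes differed between the double deletion and msn2 deletion, against 31 in young cells. These counts do not themselves test a change with age, and the direct test, given below, found 422 genes. The aged double deletion libraries also had the lowest totals, and a preparation difference of those libraries cannot be told apart from age here. SOL4 was lower in the double deletion at -2.79 ± 0.169, COX26 at -2.75 ± 0.206, STF2 at -2.47 ± 0.193, EGO4 at -2.35 ± 0.194, RGI1 at -2.31 ± 0.228 and CYC7 at -2.16 ± 0.156. Of 51 Msn2/4 stress genes 46 fell and 1 rose, with a median of -1.04: HSP12 was at -1.79 ± 0.145, TPS1 at -0.72 ± 0.151 and CTT1 at -0.73 ± 0.163. Biotin genes fell in 7 of 9, with BIO5 at -1.59 ± 0.127 and BIO2, biotin synthase, at -1.06 ± 0.0818. Histones rose in 7 of 10, and in 9 adjusted over the list alone, HTB2 by 0.64 ± 0.0876. YOR387C, VEL1, ZPS1 and MET17 of methionine synthesis were higher, by 1.43 ± 0.104, 1.39 ± 0.0918, 1.28 ± 0.117 and 1.09 ± 0.107, and FIT2 was lower at -1.47 ± 0.13. Ribosome biogenesis genes rose in 41 of 97, and in 51 adjusted over the list alone (adjusted p = 0.149 with an estimated correlation). Daughter-cell genes rose in 9 of 12 (adjusted p = 0.207 with an estimated correlation).
The lists of Msn2/4 stress genes (adjusted p = 3.98e-05), biotin genes (0.0096) and histones (0.0369) held with an estimated correlation, of 16 camera calls. The test found 1696 genes, 771 higher and 925 lower, 163 of them at least 2-fold changed, 14 higher and 149 lower, and 180 past a log2 fold change of 0.5. Without aged msn2 deletion replicate 3 the count was 1042, and without aged double deletion replicate 3 it was 1069. When scaled by library totals alone, 293 genes were higher and 1017 lower.
Across genes the effects of both deletions in aged cells correlated at Pearson r = 0.587 and Spearman rho = 0.57. Shared wild-type libraries alone gave a simulated mean r of 0.347, the covariance was 0.119 against a simulated 0.012, and divided controls gave r of 0.44 to 0.578. Of 952 and 1133 higher genes 485 were shared, against 158 for independent calls, and of 1095 and 1345 lower genes 724, against 216, with controls shared again.

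**Figure D3:**
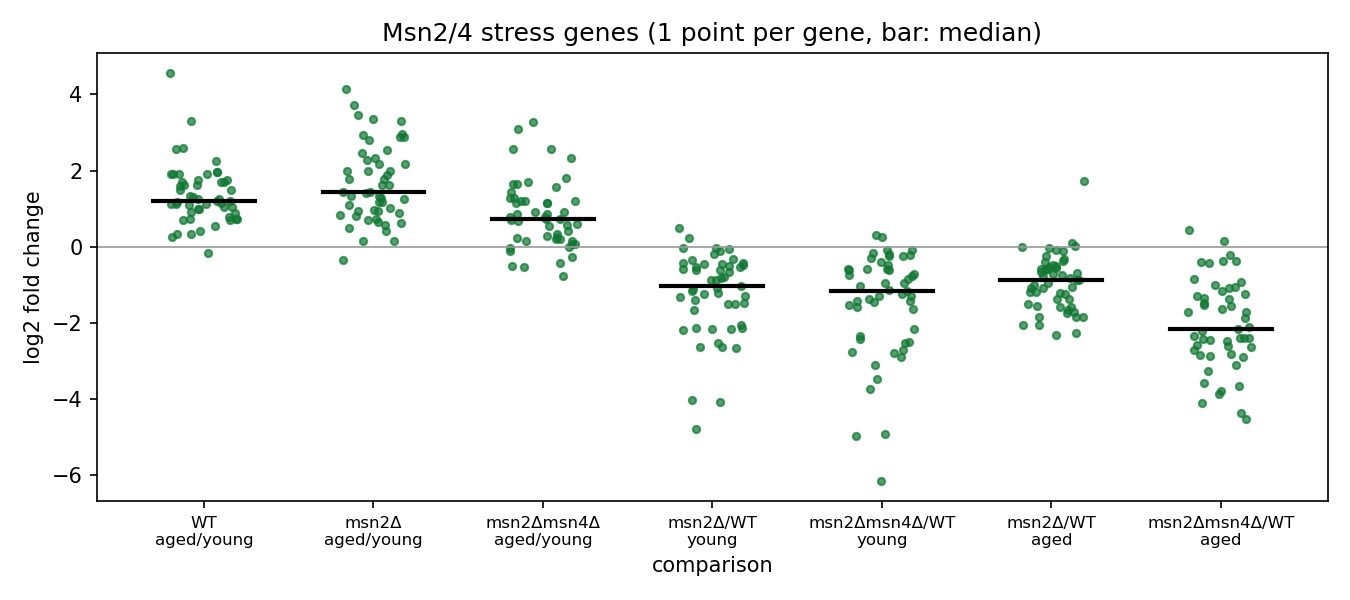
Log2 fold changes of the 51 Msn2/4 stress genes in 7 comparisons. Points are genes and bars are medians, which are 1.21, 1.43 and 0.73 for age in wild type, msn2 deletion and double deletion, -1.03 and -1.15 for the deletions in young cells, and -0.88 and -2.17 in aged cells.

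The last 3 comparisons tested whether the age effect itself differed between strains. The age effect is the signed log2 fold change of aged over young, so a lower one can be a smaller rise, a rise turned to a fall, or a steeper fall. Between msn2 deletion and wild type, the age effect was higher in msn2 deletion for HSP12 (difference of log2 fold changes 2.47 ± 0.2), DDR2 (2.44 ± 0.229), the mitochondrial kinase gene FMP48 (2.28 ± 0.202), HXK1 (2.23 ± 0.188) and HXT7 (1.90 ± 0.177), genes whose young level was low in msn2 deletion. It was lower for HSP30 (-1.88 ± 0.12), TDA6 (-1.44 ± 0.164), CIP1 (-1.29 ± 0.178), HSP26 (-1.08 ± 0.15) and HSP104, a disaggregase (-1.05 ± 0.105). Msn2/4 stress genes were divided, 15 higher and 8 lower of 51 (18 and 9 adjusted over the list alone), with a median of 0.0844 (adjusted p = 0.234 with an estimated correlation). Hsf1 chaperones, most of which fell with age in both strains, had a lower age effect in 10 of 22, with HSP78 at -0.73 ± 0.106 (adjusted p = 0.0511 with an estimated correlation), and proteasome genes in 8 of 33 (adjusted p = 0.156 with an estimated correlation). Daughter-cell genes had a lower one in 4 of 12 (adjusted p = 0.304 with an estimated correlation).
The test found 1009 genes, 515 with a higher and 494 with a lower age effect in msn2 deletion. At least 2-fold different were 92, 73 higher and 19 lower, and 51 passed a log2 difference of 0.5, 41 higher and 10 lower. Camera called 10 lists, and camera with an estimated correlation called 0, with a smallest adjusted p of 0.0511, while fry called 12. Thinning gave 474 genes, leaving out young wild type replicate 3 gave 645, and leaving out aged msn2 deletion replicate 1 gave 657. Under library totals alone 504 were higher and 180 lower. Adjusted over the list alone, 13 Hsf1, 12 proteasome and 5 daughter-cell genes had a lower age effect.
Between the double deletion and wild type, the age effect on most stress genes was lower in the double deletion. Msn2/4 stress genes had a lower age effect in 32 of 51 and a higher one in 5, with a median of -0.69: GND2 differed by -2.40 ± 0.197, SIP18 by -2.23 ± 0.301, HSP26 by -2.22 ± 0.154, EGO4 by -2.11 ± 0.255 and PGM2 by -1.53 ± 0.129, of which SIP18 and EGO4 stand outside the list. HSP12 (2.04 ± 0.207), TMA10 (1.83 ± 0.233) and DDR2 (1.65 ± 0.307) went the other way. Ribosome biogenesis genes had a higher age effect in 43 of 97, RPA12 of RNA polymerase I by 1.09 ± 0.13 and UTP30 by 0.84 ± 0.0892. Biotin genes had a lower one in 8 of 9, with BIO3 at -1.32 ± 0.0961 and BIO5 at -1.26 ± 0.174. Histones, most of which fell with age in wild type, had a higher one in 7 of 10, HTB1 by 0.74 ± 0.12 from an age effect of -0.59 ± 0.0844 in wild type (adjusted p = 0.0622 with an estimated correlation).
With an estimated correlation Msn2/4 stress and biotin genes (both adjusted p = 0.00953) and ribosome biogenesis (0.0271) held, of 10 camera calls. The test found 1104 genes, 490 higher and 614 lower in the double deletion, 142 by at least 2-fold, 118 past a log2 difference of 0.5, and 680 after thinning. With library totals alone 239 were higher and 684 lower. When adjusted over the list alone, 33 stress genes were lower and 54 biogenesis genes higher.
Between both deletion strains, the age effect on stress genes was lower in the double deletion. Msn2/4 stress genes had a lower age effect in the double deletion in 31 of 51, and in 39 adjusted over the list alone, with a median of -0.80: SOL4 differed by -1.95 ± 0.264, GND2 by -1.88 ± 0.199 and GPH1 by -1.85 ± 0.176. BDH2, a predicted butanediol dehydrogenase gene, differed by -1.99 ± 0.202. Biotin genes had a lower age effect in 6 of 9, with BIO5 at -1.87 ± 0.175, and Pho4 genes in 4 of 18, with PHO84 at -1.34 ± 0.16. Histones had a higher one in 6 of 10, HTA1 by 0.70 ± 0.145 from an age effect of -1.09 ± 0.103 in msn2 deletion. YOR387C, VEL1 and ZPS1 rose more, by 1.82 ± 0.197, 1.52 ± 0.151 and 1.41 ± 0.172, while FIT2 rose less (difference -1.40 ± 0.195).
The lists of Msn2/4 stress genes (adjusted p = 0.00016), biotin (0.000764), Pho4 (0.00202) and histones (0.0134) held with an estimated correlation, of 16 camera calls. The test found 422 genes, 117 higher and 305 lower in the double deletion, 109 by at least 2-fold and 77 past a log2 difference of 0.5. DESeq2 called 650, 288 higher and 362 lower, and thinning left 213, 59 higher and 154 lower. When scaled by library totals alone, the median moved by -0.16, and 28 genes were higher and 542 lower. Adjusted over the list alone, 7 biotin and 5 Pho4 genes were lower and 7 histones higher.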

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

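The 3 patterns weighed here, and the tests of them, were chosen only after the data were seen, except that RLE factors, library totals and removal of genes were planned as alternatives; the splits were planned. Groups hold 3 libraries each, so no test for an outlying sample was run. The third pattern compares strains in aged cells alone. The other results here are among those whose age effect differed between strains, by the edgeR test for genes and by both camera tests for lists.
RRT15 differed in its age effect by 11.97 between double deletion and wild type (adjusted p = 4.42e-12) and by 12.19 between both deletion strains (adjusted p = 3.42e-10), and all 3 aged double deletion libraries showed it. Of 4 features of nuclear ribosomal RNA, 4 were higher in every aged double deletion library than in every other aged library. RDN37-1 and RDN25-1 among them overlap in the genome, so the 4 are not separate observations. As 72.5% of RRT15 matches 25S ribosomal DNA, reads from ribosomal DNA may lie behind the RRT15 counts. Yet in the aged double deletion against aged wild type RRT15 was at 11.2, RDN25-1 at 1.2, RDN18-1 at 2.67 and RDN37-1 at 1.95. The size is thus not accounted for, and the handling of reads that match several places is unknown. After thinning to the smallest total the highest value in the other 15 libraries was 2.02 CPM, against a lowest of 2560 CPM in the aged double deletion. Thinning leaves the expected CPM unchanged, so it shows only that drawing fewer counts does not raise RRT15. It cannot test other effects tied to low library totals. Transcription of the wider locus is argued against by MAS1, the next gene, in the same comparison at -0.18 ± 0.0915, while YLR162W at 0.637 ± 0.838 lay near the floor and transcription of RRT15 alone stays open. A difference in library preparation between these 3 libraries and the rest cannot be separated from the strain, and no label gives a batch.
Msn2/4 stress genes rose with age in the double deletion (median 0.726, 33 of 51 genes), with age effects that differed from wild type by a median of -0.691 (adjusted p = 0.00953 with an estimated correlation) and from msn2 deletion by a median of -0.804 (adjusted p = 0.00016 with an estimated correlation). More MSN4 transcript in aged cells is argued against, since MSN4 counts were lower in aged than in young double deletion cells (-0.658, adjusted p = 0.000131). After thinning the median was 0.707. Thinning keeps expected fold changes, so this shows only that fewer counts alone did not make the rise. Other effects tied to low library totals were not tested. The lowest median relative to all genes over 3 scalings, 0.688, cannot test scaling, which moves all genes by about the same amount. The size of that move can: library totals moved the median of all genes by 0.427 and RLE factors by -0.0155. Against a list median of 0.726, this argues against the choice among TMM factors, RLE factors and library totals as the cause. Growth in the device on beads cannot be told apart from age, as 0 young groups went through it. Msn4 function left in the double deletion stays open, as MSN4 kept 21.4 CPM in young and 13.4 CPM in aged cells. A mixture of cells, another regulator and scaling other than TMM factors, RLE factors or library totals stay open too.
In the aged double deletion against aged wild type, 223 genes were at least 2-fold lower and 43 higher, a ratio of 5.19. Unequal counting precision is argued against by a ratio of 5.22 after thinning. Thinning keeps expected fold changes, so other effects tied to low library totals were not tested. Over the 88% of called genes with a known length, removing the trends over length and GC content gave a ratio of 6.21, from 7.07 before. This argues against them as the whole cause. Before removal the log2 fold change correlated with length (Spearman rho = 0.276). Removal took lower genes from 205 to 174 and higher ones from 29 to 28, with adjusted p-values kept from before it. Scaling is argued against as the whole cause by ratios of 5.05 with RLE factors and 2.76 with library totals, although the latter shows that it sets part of the ratio. Of the 223 lower genes, 42 belong to the Msn2/4 stress list. A preparation difference of these 3 libraries stays open here too.
The other results are given as values. The age effect of msn2 deletion differed from that of wild type in 1009 genes, with HSP12 at 2.473, DDR2 at 2.445 and FMP48 at 2.276, and HSP30 at -1.878, TDA6 at -1.443 and CIP1 at -1.293. The age effect of the double deletion differed from that of wild type in 1104 genes, with YOR387C at 2.15, HSP12 at 2.035, GND2 at -2.4, SIP18 at -2.228 and HSP26 at -2.217. Between the same strains the median difference was 0.343 for ribosome biogenesis (adjusted p = 0.0271 with an estimated correlation) and -0.72 for biotin genes (adjusted p = 0.00953 with an estimated correlation). Between both deletion strains it differed in 422 genes, with YOR387C at 1.817, VEL1 at 1.516, BDH2 at -1.992, SOL4 at -1.95 and YER067C-A at -1.943. The medians there were 0.504 for histones (adjusted p = 0.0134 with an estimated correlation), -0.269 for Pho4 genes (adjusted p = 0.00202 with an estimated correlation) and -1.01 for biotin genes (adjusted p = 0.000764 with an estimated correlation).
Other splits of the same libraries were fitted for each count. For each pairwise contrast 3 against 3 libraries make 10 splits, and 1 of them, the real one, gave as many genes, which is too few splits for a share under 0.05. The real counts were 4365, 4754 and 4179 for age in wild type, msn2 deletion and double deletion, where the highest other splits gave 0, 0 and 1. In young cells they were 2084, 2579 and 31 for msn2 deletion against wild type, double deletion against wild type and double against msn2 deletion, with 0, 2 and 0 in the highest other splits. In aged cells they were 2047, 2478 and 1696 in the same order, with 0, 0 and 0. The other splits mix both groups of a contrast, so a real difference widens the spread within each relabelled group. Low counts there follow in part from that and lend the real counts no support. For the differences of age effects, 100 of 200 splits were drawn. For msn2 deletion against wild type 3 of 100 gave as many as 1009 genes, with 2863 in the highest other split. For double deletion against wild type 8 of 100 gave as many as 1104, with 3303, and for double against msn2 deletion 9 of 100 gave as many as 422, with 1531. In all 3 the highest other split exchanged the strains of all 6 aged libraries and of 0 young ones, so it adds the deletion effects of both ages in place of subtracting them. Such splits carry the strain structure of the samples, so these shares do not measure chance, and they neither exclude it nor count for it. This reading of the splits was chosen after their counts were seen.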

How the results depend on the processing

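Thinning, removal of RRT15 along with the planned removal of genes, and the fit without the 3 aged double deletion libraries are tests chosen only after the data were seen. The other alternatives were planned. Of list medians under the alternatives, 6361 of 6526 (97.5%) kept their side of the threshold and, where called in the main fit, their direction. Another 102 were weaker, 59 stronger and 4 reversed. The list medians left out DESeq2, the fit of only the libraries of the contrast and the test against 0.5. Named genes were checked only under DESeq2, RLE factors, library totals, the replicate block and each library left out. Of their values, 20771 of 22082 (94.1%) were unchanged in the same sense, 1081 were weaker, 230 stronger and 0 reversed. Most of these genes were chosen for large changes or the smallest p of a list in the main fit, which favours agreement. Direction was not checked for values called in neither fit, so the reversals cover only values called in the main fit. Of counts and correlations, 243 of 329 stayed within their limits. Under library totals, list medians and named genes were taken relative to the shift of the median of all genes, so their agreement there follows in part from the arithmetic and says little about scaling. The aged double deletion had the lowest totals, 4078400 to 7136185 counts. Against aged wild type its simulated recovery of genes changed by 0.5 on the log2 scale was 62.7%. For the difference of age effects between double deletion and wild type it was 29.9%. That contrast takes in 4 groups, and no simulation separated this from depth. Without the 3 aged double deletion libraries the counts were 4371, 4782, 2096, 2560, 25, 2065 and 1010 for age in wild type and msn2 deletion, the 3 young comparisons, aged msn2 deletion against wild type and its difference of age effects, and 4306, 4717, 2008, 2501, 25, 1985 and 949 of those genes were shared with the fit of all libraries. The replicate block moved no count by over 1.5 times, that for age in wild type included, where all 3 pairs of libraries with the same number had correlations over 0.1. No cause was tested for the values below unless the construction of the alternative gives it.
A test against a log2 fold change of 0.5 asks for larger effects, and it called 1283, 1899 and 1334 genes for age in wild type, msn2 deletion and double deletion. It called 139, 193 and 6 in young cells for msn2 deletion against wild type, double deletion against wild type and double against msn2 deletion, and 170, 390 and 180 in aged cells. It called 51, 118 and 77 for the differences of age effects of msn2 deletion against wild type, double deletion against wild type and double against msn2 deletion. Thinning, which lowers all counts, gave 1279 for young msn2 deletion against wild type, 16 for young double against msn2 deletion, and 474, 680 and 213 for the same 3 differences. For young double against msn2 deletion, with 31 genes, DESeq2 called 85, library totals 19, and the 6 libraries alone 13, with fewer residual degrees of freedom; for the difference of age effects between both deletion strains DESeq2 called 650; the cause was not tested for DESeq2 and library totals.
Camera with an estimated correlation, which allows for correlated members, called 3, 6 and 4 lists for age in wild type, msn2 deletion and double deletion, 5, 3 and 2 in the young comparisons, 4, 2 and 3 in the aged ones and 0, 3 and 4 for the differences of age effects. Fry, which does not compare a list with other genes, called 29, 32 and 30, then 19, 21 and 5, then 26, 26 and 25 in the same order of the first 9.
Correlations over genes with a mean log2 CPM of at least 5 were 0.898 for age in wild type and msn2 deletion, 0.828 for wild type and double deletion, 0.881 for both deletion strains, 0.921 for young deletion effects and 0.652 for aged ones. Dividing wild-type libraries between comparisons, which removes the shared controls, gave 0.489, 0.628, 0.568, 0.44, 0.608 and 0.682 in young cells and 0.521, 0.537, 0.477 and 0.44 for the aged divisions that moved.
Leaving out 1 library at a time leaves a group with 2. It gave 14 to 19 genes for young double against msn2 deletion, 1042 to 1636 for aged double against msn2 deletion, where 1042 was without aged msn2 deletion replicate 3 and 1069 without aged double deletion replicate 3, and 645 to 1115 for the difference of age effects of msn2 deletion and wild type, where 645 was without young wild type replicate 3 and 657 without aged msn2 deletion replicate 1. The correlations ranged over 0.85 to 0.874, 0.758 to 0.802, 0.801 to 0.851, 0.774 to 0.862 and 0.495 to 0.623 in the order above. The median of amino acid biosynthesis genes in aged msn2 deletion against wild type, 0.0129, was -0.00287 with RLE factors and -0.029 to 0.0746 with 1 library left out, below 0 without aged wild type replicate 2 (-0.0163) and without aged msn2 deletion replicates 1 (-0.0167) and 2 (-0.029); the cause was not tested.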

Other observations

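All tests of oxygen-linked genes were chosen only after ANB1, TIR1, TIR2, DAN1, AAC3 and HEM13 had been seen. Of a list of genes linked to oxygen, most were higher in aged cells of each strain. Most members are known to be repressed by oxygen, but ROX1, a repressor induced by oxygen, and the regulator gene MGA2 are not. ROX1 was at -0.351, 0.532 and 0.712 in wild type, msn2 deletion and double deletion, and MGA2 at -0.585, -0.469 and -1.09. In wild type, 17 of 22 rose with age and 3 fell, with a median of 0.76. ANB1, a translation factor isoform, was at 3.23 ± 0.103, the cell wall mannoprotein gene TIR2 at 3.53 ± 0.179 and the fatty acid desaturase gene OLE1 at 1.56 ± 0.111. In msn2 deletion 18 rose and 1 fell, with a median of 0.75, and in the double deletion 17 rose and 2 fell, with a median of 0.828. Camera adjusted p with an estimated correlation was 0.00091, 0.00109 and 0.00159 in the 3 strains, but the list holds the 6 genes that prompted it. Without them, 11, 12 and 11 of 16 rose and 3, 1 and 2 fell in wild type, msn2 deletion and double deletion, with medians of 0.571, 0.512 and 0.675 (adjusted p = 0.0115, 0.00926 and 0.0387 with an estimated correlation). Without members of the lists fixed earlier as well, 8 of 12 rose in each strain and 3, 1 and 2 fell, with medians of 0.425, 0.512 and 0.698. Camera adjusted p was then 0.0224, 0.00454 and 0.0746, and with an estimated correlation 0.11, 0.0387 and 0.185. The medians were thus above 0 in each strain, while the call was lost in the double deletion by both tests and in wild type by the second.
A candidate explanation is low oxygen or heme in aged cells. It also asks for lower respiratory chain genes in each strain, but their medians were 0.0797, 0.22 and -0.0808, members went both ways, and the lowest, -0.0808, decides nothing. Low oxygen in the device and age itself cannot be told apart, since no young cells were grown there.
Several lists called by camera for age in wild type were also called in msn2 deletion. TCA cycle genes rose in 10 of 12 in msn2 deletion (adjusted p = 0.263 with an estimated correlation) and cell wall stress genes in 13 of 15 (adjusted p = 0.154 with an estimated correlation). Mitochondrial ribosomal proteins fell in 46 of 66 (adjusted p = 0.234 with an estimated correlation). In the double deletion cell wall stress genes rose in 12 of 15 (adjusted p = 0.169 with an estimated correlation), amino acid biosynthesis genes in 30 of 44 (adjusted p = 0.363 with an estimated correlation) and haploid and pheromone genes in 10 of 16 (adjusted p = 0.0807 with an estimated correlation). Mitochondrial ribosomal proteins fell in 44 of 66 (adjusted p = 0.301 with an estimated correlation).
The mitochondrial ribosomal RNA 21S was at 1480 ± 126 CPM (mean ± SD, 3 libraries) in young msn2 deletion, 1170 ± 176 CPM in young double deletion and 638 ± 105 CPM in young wild type.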
